A study of Homo sapiens with 3 samples.

How the data were processed

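Genomic DNA from 3 human T cell samples, 100 ng each, was cut with MspI and TaqI, bisulfite converted and sequenced, per the labels' protocols. The labels give naive pan T cells isolated from peripheral blood of healthy donors, 100 pM of the CD20 and CD3 bispecific, 1 lymphoma cell to 5 T cells, fresh lymphoma cells and antibody every 2 days, and 14 days of stimulation. The decitabine sample was primed with 300 nM of the drug for 24 h and kept in it. The labels describe no step that separates T cells from lymphoma cells before DNA extraction. Each group has 1 library.

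Reads were processed with Bismark, Bowtie2 and methylKit on the build hg38, per the submitters' processing notes; versions and settings are not given in the sources used here. Each of 3 deposited tables compares 2 libraries in windows of 1000 bp. Per the file headers, the authors gave for each window and library a coverage, which is a count of cytosine calls, and the fraction methylated. They also deposited a p-value, a q-value, a difference of fractions, the nearest gene and the distance to it. Coverage times fraction gave a whole number in every window, to within 2.27e-11, and the smallest coverage was 30 in each library, so windows under 30 calls are not part of the tables. Column names were matched to samples by the library names in the labels. They also hold the word mono, which the labels do not explain. The direction of each difference was read from the headers. The percent of windows whose deposited p-value was recovered by Fisher's exact test to within 1% was 100.0 in each table. The deposited q-value was a Benjamini-Hochberg adjusted p times a factor whose median was 0.659, 0.202 and 0.225 in the 3 tables, and 100.0% of windows lay within 1% of it. Windows in all 3 tables had the same coverage in each.

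Windows were tested with Fisher's exact test, two-sided, on methylated and unmethylated calls, with Benjamini-Hochberg adjustment over autosomal windows. A window was called at an adjusted p under 0.01 and a difference of at least 25 percentage points. Differences are first minus second library, so a negative value is a loss in the first. The X and Y chromosomes were left out. Levels carry 95% Wilson intervals, differences Newcombe intervals, and medians over windows order-statistic intervals. The Wilson and Newcombe intervals cover counting error only. The intervals of medians reflect the spread over windows, taken as independent. None covers variation between libraries. A window at 50% has a half-width of 16.8 points at 30 calls and of 6.35 points at the naive median of 234 calls. Calls on one read are not independent, so p-values are too small.

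The design fixed before the data were examined used promoters, but no transcript annotation with strand was used here. A window was instead linked to the nearest gene in the deposited table when it overlapped the gene or lay within 1500 bp of it, so linked windows can be promoters, gene bodies or flanks, and exon, intron and untranslated parts are not given. Distances are those of the deposited table: of its windows at distance 0, 98.5% overlapped the RefSeq span of the named gene, and the named window of SPI1 did not. Context was described by distance and by starting level. Of 24625 gene IDs in the table of vehicle against naive, 23999 were found in a RefSeq table of GRCh38.p14. A gene counted as higher or lower when it had called windows in that direction alone.

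The 11 gene lists, with 239 entries, were written before the data were examined. They cover effector, exhaustion and naive or memory T cell genes, T cell identity, B cell identity, myeloid and NK cell, DNA methylation, interferon, germline, imprinted and developmental transcription factor genes. Only genes with a linked window were measured, and counts of list genes refer to these. For vehicle against naive they were 10 of 21 effector, 15 of 20 exhaustion, 12 of 20 T cell identity, 16 of 21 imprinted and 11 of 16 myeloid and NK cell genes. A list's median difference was placed among 10000 random lists matched on windows per gene. This percentile describes the libraries and is not a p-value. The genes named are, per comparison, the 5 protein-coding genes with the largest gain and the 5 with the largest loss past the threshold, and up to 3 members of each list with the largest difference past it. The text gives a subset of these with values, and 1 gene that the rule names is not reported here.

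The test was checked on simulated libraries of 91773 windows with the real coverages. For vehicle against naive it recovered 85 of 100 windows lowered by 30 points and 100 of 100 lowered by 50 points. There were 0 false calls among unchanged windows. Neither dependence of calls on one read nor variation between libraries was simulated, so this 0 does not give the error rate in the real libraries. Recovery of gains was not checked. For decitabine against vehicle it recovered 90 and 100 of 100. Alternatives set before the data were examined were differences of 10 and 40 points, adjusted p of 0.05 and 0.001, windows in all 3 tables, a coverage of 20, means for medians, and distances of 500 and 2500 bp. Alternatives added after the data were examined were the deposited q, a coverage of 100, calls thinned by a factor of 10, lists matched on level, and limits set by a share of foreign DNA. Coverage along the genome was the log2 ratio of window coverage to naive, with the median autosome set to 0, printed as percent. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.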

Results

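DNA methylation was measured by reduced representation bisulfite sequencing, which reads cytosines in the CpG-rich fragments left by restriction enzymes, in 3 libraries of human T cells from healthy donors. The first library came from cells that the labels call naive pan T cells. No value here shows whether they were the naive subset alone. Levels given for naive cells below refer to this library. The second came from T cells stimulated for 14 days with a bispecific antibody that binds CD3 on T cells and CD20 on B cells, in co-culture with WSU-DLCL2 cells, an established diffuse large B cell lymphoma line, and with the vehicle. The third came from the same co-culture with decitabine, a cytidine analogue that traps DNA methyltransferases on DNA and leads to loss of methylation as cells divide. These are called the naive, vehicle and decitabine libraries. Each group had 1 library, so no value below has a replicate error, and every test compares 2 libraries and not 2 conditions. The labels do not say whether the libraries share a donor.

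The 3 libraries shared 91773 autosomal windows of 1000 bp. They held 37829507 cytosine calls in the naive library, 52622292 in the vehicle library and 41462449 in the decitabine library, and the median window had 234, 271 and 251 calls. The mean methylation level over windows was 62.1% ± 41.7 (SD over windows) in naive cells, 59.7% ± 39.8 with vehicle and 38.8% ± 25.7 with decitabine. Windows at 80% or more made up 58.0% of the naive library, 53.8% of the vehicle library and 1.36% of the decitabine library. Windows under 20% made up 30.8%, 30.8% and 30.3%. In 5 mitochondrial windows, which serve as an unmethylated control for bisulfite conversion, the level was 0.497% in the naive library (95% Wilson interval 0.439 to 0.562), 0.497% in the vehicle library (0.423 to 0.584) and 0.490% in the decitabine library (0.437 to 0.548).

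**Figure D1:**
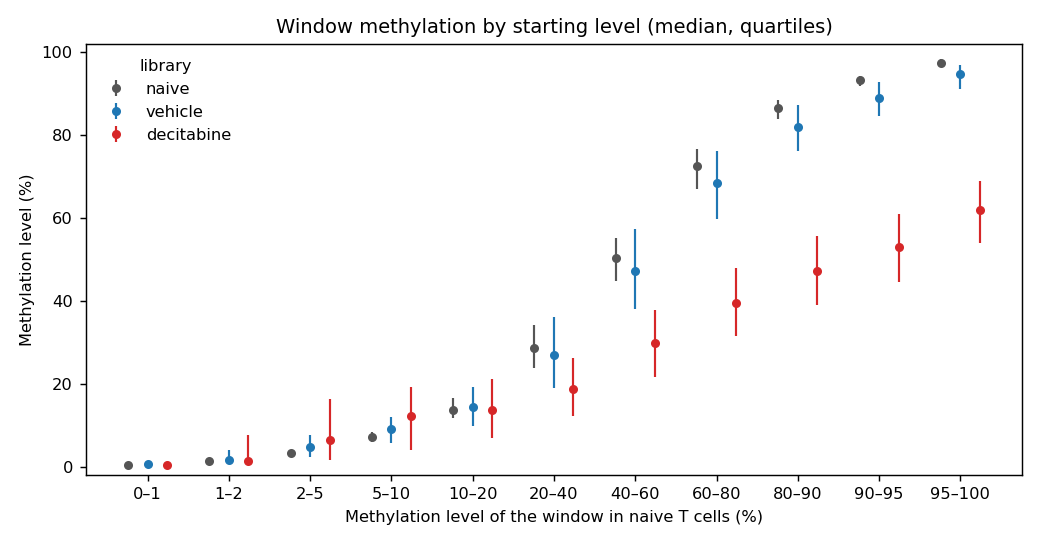
Methylation level in percent of windows grouped by their level in the naive library (x axis), with the median (point) and quartiles (line) in the naive, vehicle and decitabine libraries. Windows at 95 to 100% in naive cells had a median of 94.7% with vehicle and 61.8% with decitabine, while windows at 0 to 1% had medians of 0.4995% and 0.484%.

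The comparison of the vehicle library with the naive library asks which methylation differed after repeated stimulation without the drug. The vehicle library also differs from naive by the lymphoma co-culture, whose DNA no labelled step removes, and possibly by donor. The mix of T cell types was not measured. No difference below can therefore be credited to stimulation alone. Of 92352 windows, 255 were higher and 635 were lower in the vehicle library by at least 25 percentage points at an adjusted p under 0.01, and the median difference was -1.23 points (95% interval -1.27 to -1.19 over windows). The number depends on the size asked for: 1622 windows were higher and 6864 lower by at least 10 points, and 5802 and 11519 passed on the adjusted p alone. At the level of genes, 186 of 21381 had only higher windows and 428 had only lower windows within 1500 bp. Calls in a window come partly from the same reads. With the calls thinned by a factor of 10, 13 windows stayed higher and 28 stayed lower, so most single windows below need the full count of calls. The factor was assumed, and thinning lowers power at unchanged differences, so this drop does not measure the dependence of calls.

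Of 10 measured effector T cell genes, 2 had a window past the threshold, TBX21 and RUNX3, and both were lower with vehicle. A window in TBX21, which encodes the effector transcription factor T-bet (chromosome 17, 47734001 to 47735000), fell from 65.3% of 317 calls to 25.3% of 332 calls, a difference of -40.0 points (95% Newcombe interval -46.7 to -32.7; Fisher's exact test, adjusted p = 1.62e-22). A window in RUNX3, a transcription factor of cytotoxic T cells (chromosome 1, 24916001 to 24917000), fell from 74.4% to 38.9% (Fisher's exact test, adjusted p = 5.76e-13). The median gene difference of the effector list was -2.49 points, at percentile 9.98 of random lists matched on windows per gene and at 27.7 with level matched too. In the opposite direction, a window inside TCF7, which encodes the factor TCF-1 of naive and memory T cells (chromosome 5, 134119001 to 134120000), rose from 1.49% of 201 calls to 32.6% of 135 calls, by 31.1 points (23.3 to 39.5; Fisher's exact test, adjusted p = 1.68e-14). It was at 11.4% in the decitabine library. TCF7 was the only gene past the threshold among 15 measured genes of naive, memory and stem-like T cells.

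The other listed genes past the threshold were spread over 6 groups. A window at TET3, an enzyme that oxidises methylated cytosine (chromosome 2, 73983001 to 73984000), rose from 31.7% to 70.7% and stood at 24.4% with decitabine. HOXB4 rose from 25.5% to 66.3% and HOXA2 from 20.9% to 47.4%; both are homeobox transcription factors. The DNA sensor gene CGAS fell from 90.5% to 48.6% and the interferon-induced gene OASL from 94.0% to 67.8%. CD2, an adhesion receptor of T cells, fell from 73.5% to 46.9%, while the T cell identity list as a whole had a median gene difference of 0.526 points (percentile 98.7, and 95.04 with level matched). The testis gene BRDT fell from 93.2% to 65.7% and PAX5, a B cell transcription factor, from 95.7% to 70.2%. None of the measured genes passed the threshold among 15 exhaustion and inhibitory receptor genes, 16 imprinted genes and 11 myeloid and NK cell genes. Listed genes without a linked window were not tested. The median gene difference of the 45 developmental transcription factor genes was 3.50 points, against -0.774 points over all genes. That median lay at percentile 100.0 of 10000 random lists matched on windows per gene, and at 99.85 when the lists were matched also on the starting level.

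By the fixed rule, the protein-coding genes with the largest gains were ERICH1, PKP3, STRN, DLGAP2 and ARRB2. The ERICH1 window (chromosome 8, 688001 to 689000) rose from 0.577% of 867 calls to 76.3% of 1154 calls, and was at 58.1% with decitabine. PKP3, a desmosome protein gene, rose from 28.8% to 96.3%, and STRN, a scaffold protein gene, from 10.9% to 68.1%. The largest losses were in ASRGL1, KDM4B, GPR55, PIEZO1 and PTP4A3. GPR55, a lipid receptor gene (chromosome 2, 230944001 to 230945000), fell from 91.3% to 33.1%, and PIEZO1, a mechanosensitive channel gene, from 92.4% to 34.5%. Of the 21 windows named in this comparison, 2 stayed past the threshold with thinned calls, ERICH1 and PKP3.

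**Figure D2:**
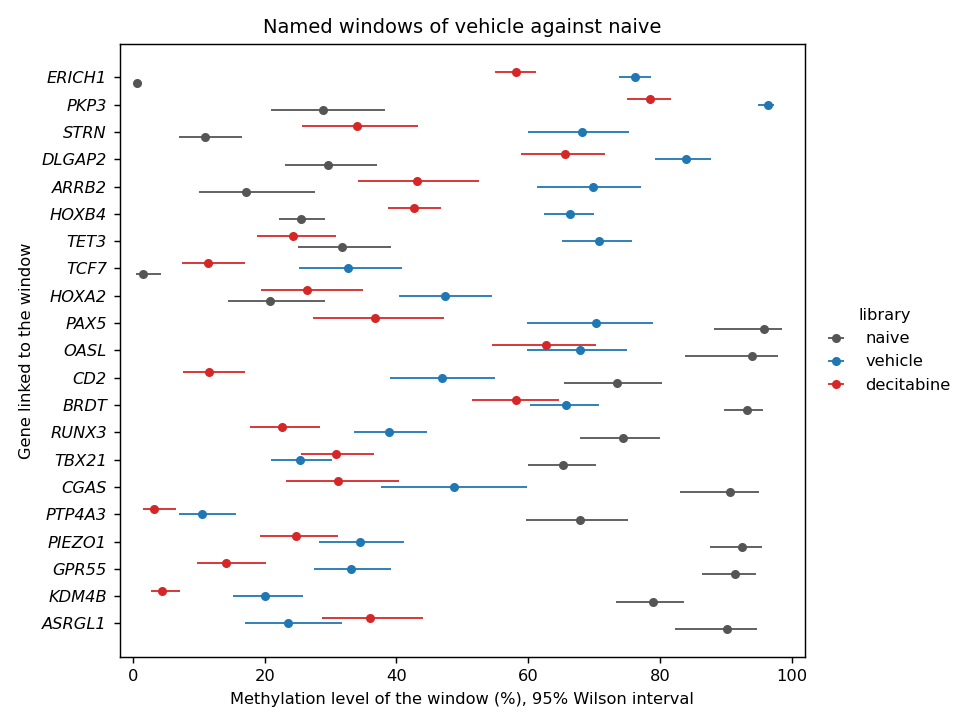
Methylation level in percent (x axis) of the 21 windows named in the comparison of vehicle with naive, by linked gene (y axis), in the naive, vehicle and decitabine libraries, with 95% Wilson intervals that cover counting error only. The TCF7 window was at 1.49%, 32.6% and 11.4%, and the TBX21 window at 65.3%, 25.3% and 30.8%.

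The comparison of the decitabine library with the vehicle library asks what differed with the drug under the same stimulation. Both libraries came from a lymphoma co-culture, and their shares of lymphoma DNA may differ. The labels do not say whether they share a donor, and the mix of T cell types was not measured. No difference below can therefore be credited to an effect of the drug on T cells alone. Methylation was lower across the genome. Of 92450 windows, 46560 (50.4%) were lower and 34 were higher with decitabine, and the median difference was -25.2 points (95% interval -25.3 to -25.0 over windows). Within 1500 bp of genes, 12349 of 21379 genes (57.8%) had only lower windows and 10 had only higher windows. Windows at 80% or more in both the naive and vehicle libraries, 48692 in number, kept a median of 64.2% of the vehicle level, and the central 90% of them kept between 44.9% and 80.9%. Only 148 kept 90% or more. With the calls thinned by a factor of 10, 8298 windows were lower and 1 was higher.

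Effector and exhaustion genes were among those that fell. Of 10 effector T cell genes, 8 were lower, including a window 1260 bp from IFNG, the interferon gamma gene (chromosome 12, 68161001 to 68162000), at 98.99% in naive cells, 89.0% with vehicle and 41.2% with decitabine. The difference from vehicle was -47.9 points (-54.6 to -40.5; 243 and 319 calls; Fisher's exact test, adjusted p = 3.53e-33). PRF1, which encodes perforin, went from 93.8% with vehicle to 46.0%. Of 15 exhaustion and inhibitory receptor genes, 9 were lower, among them TOX2 (97.6% to 45.3%), BATF (90.8% to 46.5%) and NR4A1 (82.1% to 38.6%). Of 15 genes of naive, memory and stem-like cells, 10 were lower, with SATB1 going from 94.6% to 32.6%. Over all genes 57.8% had only lower windows, and a gene needs only 1 to count. By window, 19 of 32 were lower in the effector list, 20 of 60 in the exhaustion list and 20 of 66 in the naive and memory list. Of all windows 50.4% were lower, so the exhaustion and the naive and memory lists had fewer lower windows than that share. The effector median of -21.4 points lay at percentile 15.0 of random lists matched on windows per gene and at 62.2 when level was matched too. The exhaustion median of -11.0 points lay at 92.6 and 37.5, and the naive and memory median of -11.1 points at 89.75 and 21.5.

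In the T cell identity list, 11 of 12 measured genes had a lower window, such as ZAP70 (96.5% to 44.0%). A gene needs only 1 lower window to count, and over all genes 57.8% had only lower windows. Of the 65 windows of this list 24 were lower, against 50.4% of all windows. The T cell identity median of -19.4 points lay at percentile 38.5, and at 7.51 with level matched. Among genes of DNA methylation, 10 of 12 were lower: DNMT3A fell from 93.5% to 45.6% and the TET3 window from 70.7% to 24.4%. Interferon response and nucleic acid sensing genes were lower in 10 of 14, including MX1 (98.3% to 58.3%) and IFI44 (91.7% to 42.9%). Germline genes were lower in 14 of 24, including STK31 (93.3% to 42.7%) and TDRD9 (78.5% to 31.2%). Imprinted genes were lower in 10 of 16, including MEG3 (81.0% to 31.8%) and SNRPN (85.0% to 39.3%). Lower windows were 35 of 82 for DNA methylation, 18 of 36 for interferon, 23 of 48 for germline and 27 of 84 for imprinted genes. The DNA methylation, interferon and imprinted medians lay at percentiles 73.2, 43.6 and 76.8, and at 84.1, 47.4 and 92.6 with level matched. B cell identity genes were lower in 12 of 14, with CD79B going from 91.9% to 36.3%, and myeloid and NK cell genes in 8 of 11, with ITGAX going from 90.4% to 44.7%. By window, 31 of 57 were lower in the B cell identity list and 15 of 31 in the myeloid and NK cell list. The B cell median of -23.9 points lay at percentile 6.31 of random lists and at 2.2 with level matched. The myeloid and NK cell median of -27.4 points lay at 1.22 and 2.40. The germline median of -22.8 points lay at 2.3, and at 99.49 with level matched, so its place turned with the matching. Of 45 developmental transcription factor genes, 8 were lower and 0 higher, GATA4 had windows in both directions, and 36 were not past the threshold. Their mean level with vehicle was 19.2%, and their median over genes, whether past the threshold or not, was 3.87 points against -15.6 points over all genes, at percentile 100.0, and at 98.29 with level matched.

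Among the protein-coding genes with the largest losses against vehicle were GPCPD1, GNG7, SARDH and SP140. The SP140 window, in a gene of nuclear bodies in lymphoid cells (chromosome 2, 230203001 to 230204000), went from 91.8% of 219 calls to 19.7% of 254 calls. The largest gains were in WLS, AARD, CRYM, CYP2A6 and CADPS2. AARD (chromosome 8, 116938001 to 116939000) rose from 1.87% of 107 calls to 46.2% of 199 calls, by 44.4 points (36.1 to 51.4; Fisher's exact test, adjusted p = 2.04e-18). AARD and CADPS2 lie on chromosomes 8 and 7, where coverage of the decitabine library was raised; these chromosomes held 9 of the 34 higher windows (26.5%; 14.6 to 43.1) and 10.05% of the windows tested. CYP2A6 belongs to a family of near-identical neighbouring genes, so its value is uncertain. Of 43 windows named in this comparison, 8 stayed past the threshold with thinned calls.

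A part of the windows that were low in naive cells was higher with decitabine. Of 14930 windows under 2% in naive cells with at least 100 calls in each library, 1234 (8.27%) were at 10% or more in the decitabine library, and their medians were 1.22% in the naive library, 5.48% in the vehicle library and 16.5% in the decitabine library. In the fixed lists, 28 low windows (under 10% in naive cells) of T cell identity genes had a median gain of 10.2 points over naive with decitabine and 2.52 points with vehicle. Of the 28, 18 lay in BCL11B and GATA3, and the 10 in other genes gained a median of 9.47 points with decitabine. Low windows of effector, exhaustion and naive or memory T cell genes gained medians of 0.140, 0.930 and -0.0100 points. The values were 1.25%, 6.50% and 16.8% at CD7 and 0.987%, 1.25% and 15.0% at CD247, the CD3 zeta chain gene. Low windows of B cell identity genes, 13 in number, had a median gain of -0.0638 points with decitabine. At 2 of the 13, in PAX5 and BLK, the gain was 5 points or more, while the 5 low windows of PAX5 had a median gain of -2.43 points. Low windows of developmental transcription factor genes gained a median of 10.5 points over naive, and all 23107 low gene-linked windows a median of 0.149 points. These level classes were chosen after the data were examined.

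The coverage of the decitabine library relative to naive was not even along the genome. It was 9.42% above the median autosome on chromosome 8 and 7.70% above it on chromosome 7, while the other 20 autosomes lay between -2.19% and 1.962%. The first 120 Mb of chromosome 8 stood at 13.9% (95% interval 12.5 to 14.8) and the rest of it at 1.23% (-0.0825 to 2.81). In the vehicle library the autosomes lay between -5.13% and 3.45%, with chromosome 8 at 2.41% and chromosome 7 at -1.05%. The first 120 Mb of chromosome 8 stood at 4.86% with vehicle (3.07 to 7.12) and the rest at -2.11% (-4.78 to 0.783). Single 20 Mb bins departed in both libraries. The highest bin of the decitabine library was at 18.5%, at 180 to 200 Mb of chromosome 3, where the vehicle library was at 3.02%. Bins in the first 120 Mb of chromosome 8 lay between 11.6% and 15.3% with decitabine and between -1.27% and 14.7% with vehicle. The vehicle library was at -22.2% at the start of chromosome 21 and 14.7% at 100 to 120 Mb of chromosome 8. The decitabine library was at -9.999% and 14.5% in the same bins. The vehicle library also came from a lymphoma co-culture, so it cannot be taken as free of lymphoma DNA.

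**Figure D3:**
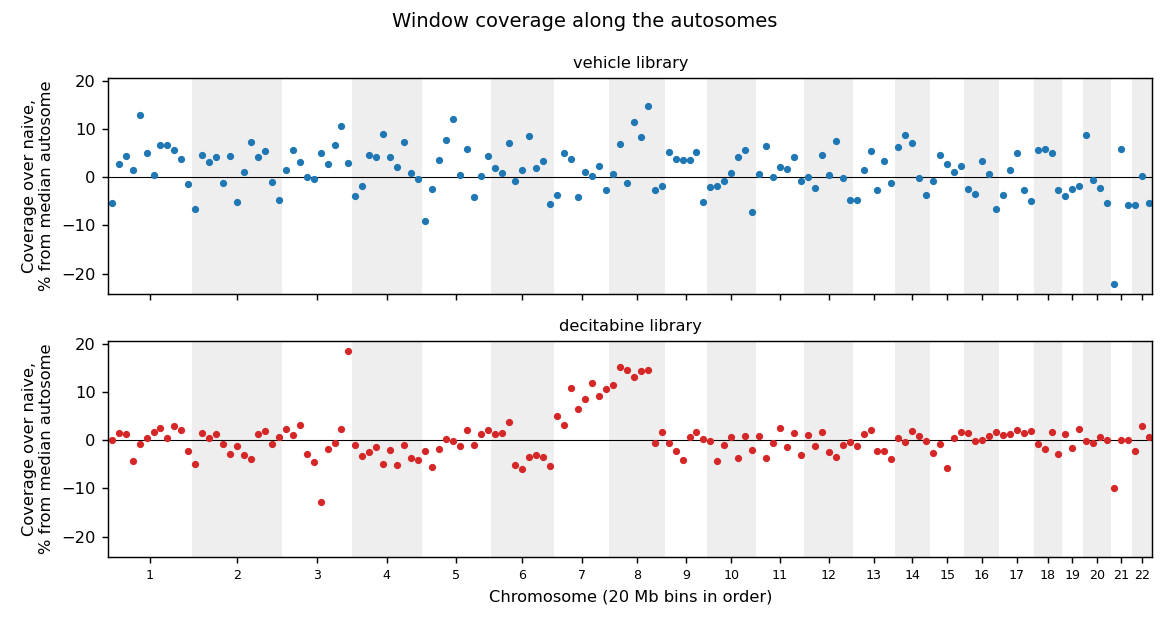
Median coverage of windows over the naive library, as percent departure from the median autosome (y axis), in 20 Mb bins in chromosome order (x axis), for the vehicle library (top) and the decitabine library (bottom); each point is 1 bin with at least 50 windows. In the decitabine library chromosomes 7 and 8 stand at 7.70% and 9.42%, and the last part of chromosome 3 at 18.5%.

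The comparison of the decitabine library with the naive library joins stimulation, lymphoma co-culture and drug. Of 92415 windows, 50151 (54.3%) were lower and 184 were higher with decitabine, and the median difference was -27.6 points. Of 21372 genes, 12718 (59.5%) had only lower windows, 69 only higher and 82 both. The largest losses were in PHYHD1 (100% to 16.5%), MDC1 (100% to 18.9%), GGNBP2 (100% to 19.8%), SLC7A5 (95.3% to 15.2%) and CCDC12 (96.3% to 17.4%). SLC7A5, which encodes an amino acid transporter induced in activated T cells (chromosome 16, 87867001 to 87868000), was at 52.2% in the vehicle library. The largest gains were in ERICH1, WLS, PKP3, AARD and CRYM. Of the 184 higher windows, 76 (41.3%; 34.4 to 48.5) lay on chromosomes 7 and 8, which held 10.1% of the windows tested. With calls thinned by a factor of 10, 99 windows were higher and 15752 were lower.

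By list, the lower genes against naive were 8 of 10 effector genes, 11 of 15 exhaustion genes, 11 of 15 naive and memory genes, 11 of 12 T cell identity genes, 12 of 14 B cell identity genes and 8 of 11 myeloid and NK cell genes. They were also 10 of 12 genes of DNA methylation, 8 of 14 interferon genes, 16 of 24 germline genes and 10 of 16 imprinted genes. Over all genes 59.5% were lower, and a gene needs only 1 lower window to count. The B cell identity median of -28.2 points lay at percentile 2.61 of random lists, and at 0.31 with level matched. The T cell identity median of -18.7 points lay at 58.25 and 40.25, and the developmental median of 8.84 points at 100.0 and 100.0. RUNX3 went from 74.4% to 22.7%, IRF4 from 85.0% to 27.8%, CD2 from 73.5% to 11.5% and CGAS from 90.5% to 31.2%. Of 45 developmental transcription factor genes, 8 were lower and 5 were higher. The 5, named after their values were seen, were PAX6 (3.21% to 31.6%), SIX2 (0.806% to 27.8%), EN2 (5.52% to 34.0%), DLX5 (10.5% to 37.1%) and SOX17 (6.86% to 34.6%). EN2 and DLX5 lie on chromosome 7 and SOX17 on chromosome 8, where coverage was raised. GATA4, on chromosome 8, and the imprinted gene GRB10, on chromosome 7, had windows in both directions.

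Differences between vehicle and naive were set beside those between decitabine and vehicle over all 3 libraries. Of the 255 windows that were higher with vehicle than in naive cells, 154 (60.4%) were lower with decitabine than with vehicle, against 129 expected of independent lists. Simulated unchanged libraries gave 0 such windows, but the test made 0 false calls in unchanged simulated windows, so that value was fixed in advance and sets no benchmark for the shared vehicle library. Their median levels were 28.3% in naive cells, 62.0% with vehicle and 32.9% with decitabine. In the decitabine library 21 of them were still higher than naive, 229 were not past the threshold, and 5 were lower than naive. The 5 lay at USP2, RNF213, C2CD2, ASH2L and LOC101929540. The gained windows kept a median of 52.9% of the vehicle level, and windows matched on that level kept 59.2%. The gained windows were picked for a high vehicle value, and the matched windows were not. Upward error in the vehicle library alone would lower the share kept, so this contrast is not taken as extra loss. Of the 635 windows lower with vehicle, 158 (24.9%) were lower again with decitabine, against 322 expected. Their medians were 80.6%, 46.2% and 29.8%. The expected numbers count all windows, of which 30.8% were under 20% with vehicle and could not fall by 25 points. Every gained window was at 25% or more with vehicle, so 129 is too low a benchmark. The 635 lower windows stood at a vehicle median of 46.2%, which the 322 does not take into account. Both comparisons also use the vehicle library, so neither departure from the expected number is taken as a shared effect.

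The loss with decitabine was present in every distance class and on each autosome. Windows overlapping a gene were lower against vehicle in 47.5% of 68004 cases, and windows over 10000 bp from a gene in 66.2% of 11698. The median difference by autosome ranged from -29.7 points on chromosome 22 to -19.99 points on chromosome 6, where the naive means were 69.1% and 56.1%. Among windows at 80% or more in naive cells, the median was 96.2% in the naive library, 92.5% in the vehicle library and 58.2% in the decitabine library, and 80.4% were lower against vehicle.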

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

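All tests in this part were chosen after the results were seen. Coverage, which the methylation comparisons do not use as an outcome, was raised in the decitabine library on chromosome 7 by 7.70% and on chromosome 8 by 9.42% over the median autosome. The widest departure of any autosome in the vehicle library was -5.13%, on chromosome 21. Of single segments, chromosome 3 beyond 180 Mb stood at 18.5% (15.0 to 22.5) and chromosome 3 from 100 to 120 Mb at -12.8% (-15.5 to -7.37) in the decitabine library, and the vehicle library was at 3.02% and 4.95% there. Bins of 20 Mb also departed in the vehicle library, with -22.2% at the start of chromosome 21 and 14.7% at 100 to 120 Mb of chromosome 8. The decitabine library was at -9.999% and 14.5% there. The vehicle library was also at 12.9% at 80 to 100 Mb of chromosome 1 and 12.2% at 80 to 100 Mb of chromosome 5. Bins of this size thus vary in both libraries, and the tests on coverage use whole chromosomes.

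Against incomplete bisulfite conversion as the cause of the first pattern, that windows low in naive T cells were higher in the decitabine library, stands the mitochondrial level of 0.490%, whose upper limit lies 0.0511 points above the naive level. A candidate explanation is DNA of WSU-DLCL2 cells, which no step in the labels removes: a lymphoma line can carry extra chromosome copies, as the departure of 9.42% on chromosome 8 would need, and of windows called higher against naive 41.3% lay on the chromosomes with raised coverage, against 11.8% (8.37 to 16.3) of those called higher with vehicle. Low T cell identity windows gained a median of 10.2 points against -0.0638 points in B cell identity windows. As medians over 9 and 7 genes these were 12.3 and 0.0510, and the lists share 0 genes. A window in BLK and 1 in PAX5 go against the split, though the 5 low windows of PAX5 had a median gain of -2.43 points. IRF8 in the B cell list is also used by activated T cells. The contrast between these lists does not single out T cell genes. Low windows of the effector, exhaustion and naive or memory lists gained 0.140, 0.930 and -0.0100 points. Those of developmental transcription factors, which mark no blood lineage as a group, gained 10.5 points. Methylation gained by the T cells themselves cannot be told apart from this as a part of the pattern, since the same windows gained a median of 4.26 points in the vehicle library and both explanations allow that.

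The second pattern is the loss in methylated windows with decitabine. Dilution by unmethylated lymphoma DNA as the whole cause would need a share of 35.8% at the median methylated window and of 63.3% at the lowest 1% of windows. Methylated windows, 48692 in number, kept a median of 64.2% of the vehicle level, with an upper quartile of 71.4%. Of these windows, 70.6% kept under 70% of the vehicle level, and only 1% kept more than 86.8%. Dilution as the whole cause would need lymphoma DNA less methylated than T cell DNA at nearly all of them. Of windows lower against vehicle, 10.3% (10.07 to 10.6) lay on the chromosomes with raised coverage, against 10.05% of those tested. The loss was hardly concentrated there, but how far extra copies would concentrate it was not tested. Dilution cannot be told apart from loss in the T cells, because the methylation and copy number of the lymphoma cells were not measured here. No upper limit of their share was set. The effect of decitabine on the T cells, which the design names, stays open and untested with 1 library per group.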

How the results depend on the processing

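The settings with thinned calls, a coverage of 100, the deposited q and limits for foreign DNA were chosen after the data were examined. No count or median changed direction, and counts stayed within 1.5 times under adjusted p of 0.05 or 0.001, the deposited q, windows in all 3 tables and distances of 500 or 2500 bp. A coverage of 20 and an overlap of 1 bp moved nothing, since the tables start at 30 calls on a common grid, and say nothing about stability. No paired analysis was possible because each group has 1 library. With a difference of 10 points, windows higher and lower numbered 1622 and 6864 for vehicle against naive; 4984 were higher for decitabine against naive and 2968 for decitabine against vehicle. Genes higher and lower were then 885 and 2977 for vehicle against naive, and genes higher were 1199 and 813 for decitabine against naive and against vehicle. The windows gained with vehicle and lower with decitabine became 1107, and those lower in both 5385. With 40 points, windows higher and lower were 34 and 81, 12 and 22418, and 2 and 13365 in the comparisons of vehicle with naive, decitabine with naive and decitabine with vehicle. With calls thinned by a factor of 10 they were 13 and 28, 99 and 15752, and 1 and 8298. A coverage of 100 left 20 windows higher in decitabine against vehicle. These counts move because each setting by its construction lets more or fewer windows pass. The mean in place of the median was -2.36, -23.1 and -20.7 points, and the cause was not tested. Windows that kept under 60% of the other library's level numbered 28399 against naive and 23335 against vehicle. Windows above what a 30% share of fully methylated DNA gives numbered 65 against naive, and above a 40% share 21 against naive and 4 against vehicle. Depth limits single windows: of windows named with vehicle, 2 of 21 stayed past the threshold with thinned calls, with decitabine against naive 21 of 43, and against vehicle 8 of 43.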

Other observations

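The rise of low windows in the decitabine library varied by chromosome segment, in values chosen after the data were examined. Of windows under 2% in naive cells, 30 of 419 (7.16%; 5.06 to 10.04) reached 20% or more with decitabine in the first 120 Mb of chromosome 8 and 37 of 763 (4.85%; 3.54 to 6.61) on chromosome 7. In the rest of chromosome 8 the share was 2.22% (0.759 to 6.33), and on the other autosomes 1.98% (1.76 to 2.22). The median ratio of the vehicle gain to the decitabine gain was 0.270 in the 1234 windows at 10% or more with decitabine. The 99th percentile of low windows was 22.8% with decitabine and 8.89% with vehicle.

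Lineage genes that rose in low windows with decitabine included BCL11B, which fixes T cell fate (0.529% in naive cells, 7.76% with vehicle, 21.2% with decitabine), GATA3 (0%, 5.14% and 22.7%) and UBASH3A (0%, 2.22% and 19.7%). LCK did not follow, at 2.16%, 0.539% and 1.03%. Among B cell genes, EBF1 was at 1.76%, 5.36% and 1.78%, CR2 at 0.637%, 1.90% and 1.499%, and PAX5 had a window at 2.63%, 7.81% and 24.8%. The 5 low windows of PAX5 had a median gain of -2.43 points with decitabine, so the printed window does not stand for the gene. The windows printed in this paragraph are those with the largest gain in each gene, chosen after their values were seen.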
